A study of Oryza sativa with 3 samples.

How the data were processed

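The data comprised 3 DAP-seq libraries from rice, 2 with OsWRKY11-Halo and 1 with GFP-Halo, and a peak list for each OsWRKY11-Halo library. Groups were taken from the sample titles and the treatment protocol, which ties the SYZ titles to OsWRKY11-Halo and spells the control DDZ where its title reads DZZ. The replicate numbers are those of the titles. Per the labels' protocols, both proteins were made in vitro and reacted with a genomic DNA library of the cultivar Nipponbare. The extract protocol of the same samples also mentions formaldehyde fixation of shoots of plants that express a Myc-tagged OsWRKY11, a step that belongs to another kind of assay, and how far it applies to these libraries is not settled by the labels.

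Per the submitters' processing notes, Trimmomatic 0.36, BWA 0.7.12-r1039 and MACS2 2.2.7.1 were used, with no role, order or options given. The genome build, read totals and read filters are not given in the sources used here. The peak names in the deposited lists show that each OsWRKY11-Halo library was called separately against the same GFP-Halo library. Per the file headers, each peak has a start, an end, a summit, a pileup, a fold enrichment, and a p-value and q-value on the -log10 scale. The deposited pileup is a coverage signal, a whole number of OsWRKY11-Halo fragments at the summit, with no scaling seen in its values. The deposited fold enrichment is a ratio of the pileup to the local background, each raised by a pseudocount of 1. The deposited -log10 p equals the upper Poisson tail of the pileup on that background: recomputed from pileup and fold, it came within 0.01 of the deposited value for 100% of peaks in both lists. The lists contain no fold under 2.00, and their lowest -log10 p was 2.020 in replicate 1 and 2.018 in replicate 2, while q-values run up to 0.644 and 0.530. The values thus point to a bound on fold and p rather than on q in the authors' calling, whose options are not given in the sources used here. These scores are the authors' own per peak, and were used to describe, rank and filter peaks.

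The local GFP-Halo background of each peak was computed as the pileup plus 1, divided by the fold, minus 1. Peaks within 0.001 of the lowest background of their list were counted as being on the lowest background. Above it, 55.2% of the 6417 backgrounds below 6 in replicate 1 and 60.2% of the 9781 in replicate 2 were whole multiples, within 0.01, of a step of 0.320 and 0.343. If that step is the worth of a GFP-Halo fragment after scaling by depth, the GFP-Halo library was 3.12 times as deep as replicate 1 and 2.91 times as deep as replicate 2. Poisson intervals of pileups and Wilson intervals of shares, both at 95%, cover counting error only, and sequenced fragments without molecular identifiers are not independent molecules. The lists differed in number, positions and values of peaks, so the libraries were counted as 2.

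A replicate 1 peak was called shared when a replicate 2 peak overlapped it over at least 50% of the shorter peak. Where several did, the partner with the nearest summit was taken, a choice made after seeing the data, because the longest overlap had tied a strong peak of chromosome 10 to a neighbour of its own partner; 14 pairs differ between these choices. Chance was measured with 1000 circular shifts of the replicate 2 peaks within chromosomes (one-sided permutation test), whose ends were set at the last peak. Peak strength was compared by Spearman's rho and Pearson's r of log2 fold enrichment, with intervals from Fisher's transformation and no p-value. Shares of classes of peaks were compared by two-sided Fisher's exact test. The overlap step was tested on simulated lists of 15980 and 21447 peaks: with true shared shares of 0, 10 and 30%, the excess over shifted lists was -0.156, 9.84 and 29.6%. The simulated pairs were copies of a peak at the same length, moved only slightly, at random positions and with no shared control. Real pairs had summits a median of 58 bp apart. The simulation thus tests the counting of overlaps and not the recovery of real pairs. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

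The sites named are the 5 shared peaks with the highest fold in the weaker replicate, a rule fixed before the data were examined, while the choice of partner it rests on was not; 4 of the 5 are also named with the longest-overlap partner. The same plan held tests of promoter location, of W-box and control motifs at summits, and of 21 gene lists, and it named further genes by their promoter peaks. These tests were not run, since a genome sequence and annotation in the build of the lists were not used here. A gene table of the assembly ASM3414082v1 was at hand, but that assembly is not shown to be the build of the lists, and its coordinates were not used. Alternatives planned before the data were examined were other overlap rules, stricter thresholds, the reverse direction and other measures of strength. Added later were a q-value of at most 0.05, peaks on the lowest background, shifts of 5 to 50 kb, the partner with the longest overlap and peaks with a pileup under 40.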

Results

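OsWRKY11 is a rice member of the WRKY family of plant transcription factors, proteins known to bind the W-box element in promoters, and the series concerns its effect on heading (flowering) at low and at high concentrations. The binding of OsWRKY11 to rice DNA was measured in vitro by DNA affinity purification sequencing (DAP-seq). In this assay a tagged protein made outside the cell is incubated with a library of fragmented, naked genomic DNA, and the DNA that stays with the protein is sequenced. The 3 libraries comprised 2 reactions with OsWRKY11 fused to the Halo tag, called replicate 1 and replicate 2, and 1 reaction with green fluorescent protein fused to the same tag (GFP-Halo), which served as the background. Nothing in the sample descriptions says that the 2 OsWRKY11-Halo reactions came from separate protein or DNA preparations, so the spread between them may be technical.

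The authors' peak lists held 15980 peaks for replicate 1 and 21447 for replicate 2, each called against the same GFP-Halo library. The peaks were narrow, with a median length of 161 bp (range 113 to 1239 bp) in replicate 1 and 159 bp (range 111 to 1143 bp) in replicate 2, and together they covered 3014800 bp and 3979632 bp. Depth was low at most peaks. The median pileup, the number of OsWRKY11-Halo fragments stacked at the summit, was 11 in both lists, and it lay under 20 in 98.3% of replicate 1 peaks and 98.4% of replicate 2 peaks. The deposited fold enrichment over GFP-Halo ranged from 2.00 to 8.19 with a median of 2.81 in replicate 1, and from 2.00 to 8.12 with a median of 2.71 in replicate 2. Fold enrichment reached 5 at 47 peaks of replicate 1 and 25 peaks of replicate 2. A q-value of at most 0.05 was reached by 4786 peaks (29.9%) in replicate 1 and 6058 peaks (28.2%) in replicate 2, and the largest q-values kept in the lists were 0.644 and 0.530. The replicate 2 list held 1.34 times as many peaks as that of replicate 1. The spacing of the recovered backgrounds was 1.07 times as wide in replicate 2, which equals the ratio of depths only if that spacing is the worth of a GFP-Halo fragment after scaling.

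The first comparison asked which genomic sites were recovered in both OsWRKY11-Halo reactions. A total of 2805 of the 15980 replicate 1 peaks (17.6%, 95% Wilson interval 17.0% to 18.2%) were overlapped by a replicate 2 peak over at least 50% of the shorter peak. Random shifts of the replicate 2 peaks along their chromosomes left 210 overlaps on average (1.32%), so that the observed number was 13.3 times that of shifted positions. None of the 1000 shifts gave more than 252 overlaps (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). In the other direction, 2803 of the 21447 replicate 2 peaks (13.1%) were overlapped by a replicate 1 peak. The summits of paired peaks lay a median of 58 bp apart, and in 70.4% of pairs within 100 bp. Both lists rest on the same GFP-Halo library, and part of the excess over shifted positions may come from that shared control, which could not be divided.

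The recovered share depended on how strongly a site was enriched. Of the replicate 1 peaks with a fold enrichment from 2 to 2.5, 11.3% had a partner in replicate 2 (95% Wilson interval 10.2% to 12.5%, n = 2867 peaks). The share was 19.1% (18.0% to 20.3%, n = 4242) for folds from 3 to 3.5 and 48.0% (44.0% to 52.0%, n = 602) for folds from 4 to 5. It reached 76.6% (62.8% to 86.4%), or 36 of 47 peaks, at folds of 5 and above. The shares of replicate 2 peaks with a partner in replicate 1 rose over the same classes as well, from 7.95% (7.33% to 8.62%, n = 6782) for folds from 2 to 2.5 to 41.3% (36.2% to 46.6%, n = 341) for folds from 4 to 5 and 64.0% (44.5% to 79.8%), or 16 of 25, at 5 and above. Of the 100 strongest peaks of each list, 67 (57.3% to 75.4%) of replicate 1 and 52 (42.3% to 61.5%) of replicate 2 had a partner. The mean share of replicate 1 peaks after shifts stayed between 1.22% and 1.86% over all of the fold classes. Peaks with a q-value of at most 0.05 had a partner more often than the remaining peaks, at 30.9% against 11.9% in replicate 1 (odds ratio 3.32, two-sided Fisher's exact p = 3.84e-171) and 22.8% against 9.23% in replicate 2 (odds ratio 2.91, p = 1.2e-142). Neighbouring peaks are not independent, so these p-values describe the lists rather than repeated experiments. A fold enrichment of at least 3 in both lists was found at 855 shared peaks, of at least 4 at 48 and of at least 5 at 5.

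**Figure D1:**
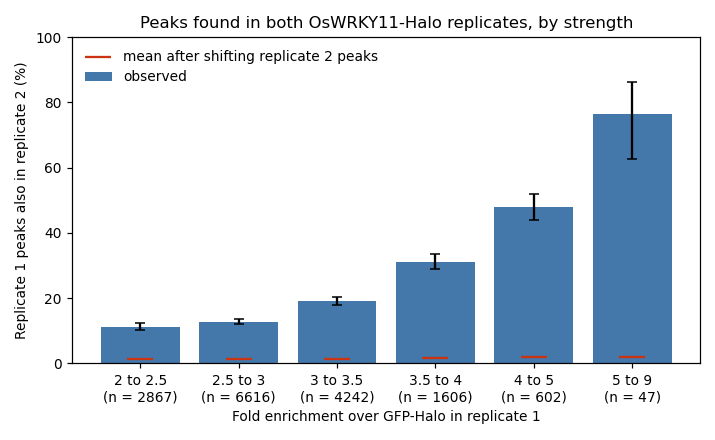
Share of replicate 1 OsWRKY11-Halo peaks that were overlapped by a replicate 2 peak (y axis, percent), by fold enrichment over GFP-Halo in replicate 1 (x axis, with the number of peaks per class); bars give the observed share with its 95% Wilson interval and red lines the mean after 1000 shifts of the replicate 2 peaks. The share rises from 11.3% in the weakest class to 76.6% in the strongest, while the shifted lists stay under 2%.

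The strength of the shared peaks was then compared between the replicates. Across the 2805 pairs, the Spearman correlation of fold enrichment was 0.305 (95% interval 0.271 to 0.338) and Pearson's r of log2 fold enrichment was 0.333. Pairs formed by chance after 100 shifts gave a rho of -0.00702. Real pairs share the GFP-Halo background that enters the fold in both lists, and shifted pairs do not. Part of the 0.305 may therefore come from the control, and rho was 0.208 among pairs on the lowest background in both lists. These correlations are across peaks of a pair of libraries, and peaks are not independent replicates. The rho of fold enrichment was 0.496 (0.445 to 0.544) among the 889 pairs with a q-value of at most 0.05 in both lists, a subset chosen after the data were seen. The q-value depends on the shared background as well as on the fold, so the control may contribute to this rho too. With a pileup near 11 at most peaks, counting error alone is broad: a pileup of 21 has an exact 95% Poisson interval from 13.0 to 32.1.

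**Figure D2:**
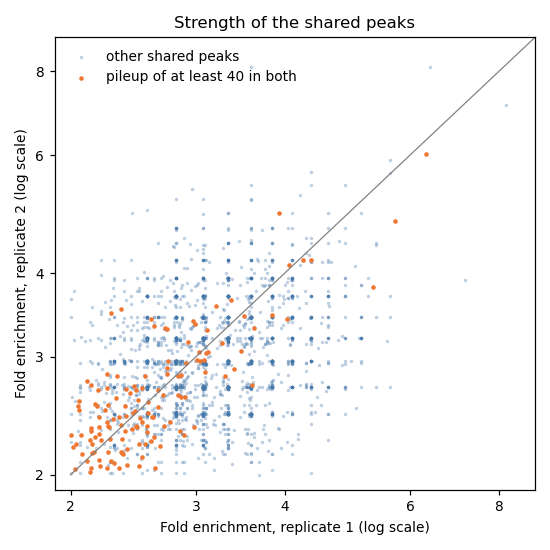
Fold enrichment over GFP-Halo of the 2805 shared peaks in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), with the line of equal values; orange points are pairs with a pileup of at least 40 fragments in both lists. Most pairs lie between 2-fold and 4-fold in both replicates with wide scatter around the line (rho 0.305), and 5 pairs reach 5-fold in both.

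The 5 shared sites with the highest fold enrichment in the weaker of the 2 replicates lay on chromosomes 10, 4, 11 and 6. Coordinates are those of the deposited lists, whose genome build is not given in the sources used here, so the sites are given by position and not by gene. The strongest was a site on chromosome 10 at 7646355 to 7647196, with a fold enrichment of 8.19 in replicate 1 and 7.14 in replicate 2 (7.66 ± 0.743, mean ± SD, n = 2) and summits 10 bp apart. Its rank rests on the partner with the nearest summit, a choice made after seeing the data: paired by the longest overlap, it would have a replicate 2 fold of 2.69 and rank 1729, and a site on chromosome 11 at 23686862 to 23687295 with folds of 5.12 and 4.92 would join the other 4. Its pileups were 31 (exact 95% Poisson interval 21.1 to 44.0) and 28 (18.6 to 40.5). The next, also on chromosome 10 at 6078442 to 6079230, had 6.40-fold and 8.12-fold enrichment (7.26 ± 1.22, SD, n = 2) with both summits at 6078989. The means of these sites differed by less than the spread between replicates.

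A site on chromosome 4 at 9156287 to 9156600 followed with 6.32-fold and 6.03-fold enrichment (6.17 ± 0.208, SD, n = 2) and a common summit at 9156424. It differed from the other 4 in depth: its pileups were 303 (269.8 to 339) and 305 (272 to 341), and its GFP-Halo background was 16.2 and 16.3 times the lowest in the lists. The sites on chromosome 11 at 13603419 to 13603602 and on chromosome 6 at 26525769 to 26525924 were enriched 5.63 ± 0.00721 and 5.77 ± 0.196 times (SD, n = 2), with pileups of 21 and 24 at the former and 21 and 23 at the latter. Outside this rule, the second-highest fold of replicate 1, 7.16 on chromosome 3 at 4300141 to 4300441, was singled out after its values were seen. Its partner in replicate 2 had a summit 1 bp away and a fold of 3.91. Among the 25 strongest pairs, with a lower fold between 4.19 and 7.14, 14 had the lowest GFP-Halo background in both lists, and the 25 were spread over 9 chromosomes.

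Shared sites were found along all 12 rice chromosomes. Their density ran from 6.46 per Mb on chromosome 6 (exact 95% Poisson interval 5.60 to 7.42) to 9.09 per Mb on chromosome 1 (8.21 to 10.03), with each chromosome measured up to its last peak. Each of the 368 whole 1 Mb windows held at least 1 shared peak, with a median of 7. The variance of shared peaks per window was 1.89 times their mean, so the Poisson intervals of density are too narrow. The window with the highest count was 10000001 to 11000000 on chromosome 10 with 29, and of its replicate 1 and replicate 2 peaks 27 and 35 had a pileup of at least 40. It was followed by 24 shared peaks between 5000001 and 6000000 on chromosome 12, where 16 and 23 peaks had such a pileup. The windows from 26000001 to 27000000 on chromosome 11 and from 20000001 to 21000000 on chromosome 7 came next with 23 and 22 shared peaks and no peak of that height. Across windows, the number of peaks in the lists correlated with a Pearson's r of 0.660 and a rho of 0.633, and windows, like peaks, are not independent replicates.

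**Figure D3:**
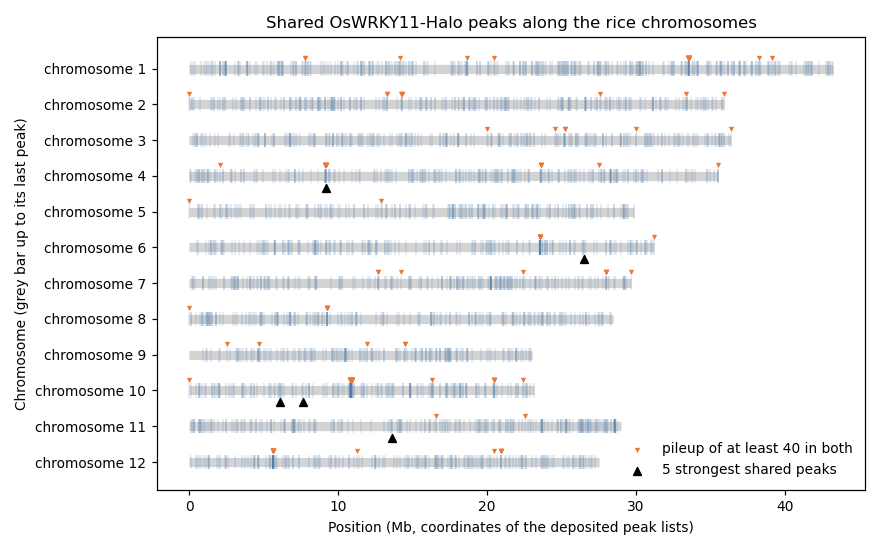
Position of the shared OsWRKY11-Halo peaks (blue ticks) along the 12 rice chromosomes (x axis, Mb in the coordinates of the deposited lists; grey bars end at the last peak); orange triangles mark pairs with a pileup of at least 40 in both lists and black triangles the 5 strongest shared peaks. Shared peaks occur on every chromosome, with 29 in the 1 Mb window of chromosome 10 that holds the densest group of high pileups.

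In a comparison added after seeing the data, the GFP-Halo background under the peaks was examined, because a low background raises fold enrichment without more OsWRKY11-Halo fragments. The background recovered from the deposited values stood at its lowest level, 2.91 fragments in replicate 1 and 3.06 in replicate 2, under 58.2% and 52.8% of peaks. A single value under so many peaks may be a lower bound set in calling. The GFP-Halo coverage under these peaks may thus be lower, and may differ between them. Most raised backgrounds were still below 6 fragments, 6417 of 6682 in replicate 1 and 9781 of 10117 in replicate 2. Peaks on the lowest background had a partner in 17.7% of cases in replicate 1 and peaks on a raised background in 17.4% (odds ratio 1.02, two-sided Fisher's exact p = 0.689). The shares in replicate 2 were 13.1% and 13.0% (odds ratio 1.01, Fisher's exact p = 0.903). These results rest on about 1% of the peaks, those with a pileup of at least 40, which all had a raised background and mostly had a partner. Without them, peaks on the lowest background had a partner slightly more often than those on a raised one, at 17.7% against 15.7% in replicate 1 (odds ratio 1.15, Fisher's exact p = 0.00162) and 13.1% against 11.9% in replicate 2 (odds ratio 1.11, Fisher's exact p = 0.010). These classes were not matched for fold, and no peak on the lowest background had a fold under 2.30 in replicate 1 or 2.21 in replicate 2. Background and fold are thus not told apart here. Neighbouring peaks are not independent, so the p-values describe the lists only. Among the 1304 pairs on the lowest background in both lists, where the background that enters the fold is a constant, the correlation of fold enrichment was 0.208 (0.155 to 0.259), lower than over all pairs.

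A small class of peaks had far higher pileups, on a background that was raised as well. A pileup of at least 40, a bound chosen after the values were seen, was reached by 184 peaks in replicate 1 and 223 in replicate 2. They included 106 of the 109 peaks of replicate 1 and 126 of the 128 peaks of replicate 2 with a -log10 q of at least 10, so that the ranking by q-value led with these peaks. Their median fold enrichment was 2.39 and 2.40, against 2.81 and 2.71 for the remaining peaks, and their median background was 16.1 and 14.8 times the lowest. They had a partner in the other list more often than the remaining peaks, at 76.1% against 16.9% in replicate 1 (odds ratio 15.7, two-sided Fisher's exact p = 1.74e-68) and 62.8% against 12.5% in replicate 2 (odds ratio 11.8, p = 6.74e-68). Many of these peaks are neighbours, so these p-values also describe the lists only.

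**Figure D4:**
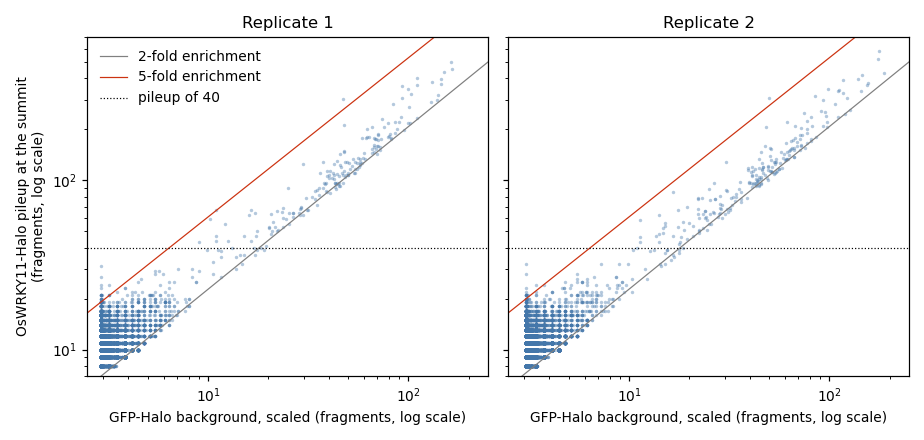
OsWRKY11-Halo pileup at the summit (y axis, fragments, log scale) against the scaled GFP-Halo background (x axis, fragments, log scale) for every peak of replicate 1 (left) and replicate 2 (right); the lines mark 2-fold and 5-fold enrichment and the dotted line a pileup of 40. The 184 and 223 peaks above the dotted line lie mostly close to the 2-fold line, with median folds of 2.39 and 2.40, on a background of at least 3.09 and 3.59 times the lowest.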

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

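Chosen only after the results were seen were the tests at a q-value of at most 0.05, on the lowest background, with shifts of 5 to 50 kb, with the longest-overlap partner and at a pileup under 40. The share of peaks found in the other list stayed above that of shifted lists in all 9 alternatives, 8 on replicate 1 peaks and 1 on replicate 2 peaks, and ranged from 10.6% (5 of 47 peaks, fold of at least 5 in both lists) to 73.4% (80 of 109 peaks, -log10 q of at least 10 in both). The lower share is limited by replicate 2, which held 25 peaks with such a fold. Of the 109 peaks behind the higher share, 106 had a pileup of at least 40. The rho of peak strength stayed above 0 in all 7 alternatives, with an interval from -0.0442 to 0.991 at a fold of at least 5. It was 0.344 for -log10 q, 0.401 for pileup, 0.347 with an overlap of 50% of both peaks, 0.872 at a fold of at least 5 (5 pairs), 0.496 at a q-value of at most 0.05 and 0.208 on the lowest background. The pileup of a called peak has to exceed a background from the control that both lists share. Part of the rho for pileup, and for the -log10 q drawn from it, may therefore come from the control. The cause of the differences between these rho values was not tested. The odds ratio of a partner on the lowest against a raised background rose from 1.02 to 1.15 in replicate 1 and from 1.01 to 1.11 in replicate 2 at a pileup under 40, and passed the test only there, as the peaks left out were 76.1% and 62.8% shared on a raised background. Other promoter lengths, motif windows, motifs, motif backgrounds and gene list settings were not run, as the tests they vary were not. Leaving out a replicate leaves no overlap to compute. No paired analysis was possible because there is 1 GFP-Halo library and both lists were called against it. The median pileup was 11 in both lists, and the effect of depth was not tested.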

Other observations

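The bound of 40 on the pileup, the test of the background under those peaks, the tests on peaks at the lowest background, the shifts of 5 to 50 kb and the Fisher's exact test on chromosome starts were chosen only after the results they describe were seen.

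Many of the peaks with a pileup of at least 40 lay in close groups. Chromosome 10 held 36 of the 184 in replicate 1 and 50 of the 223 in replicate 2. Of these, 27 lay in a stretch from 10808721 to 10920850 in replicate 1, and 35 from 10806817 to 10920846 in replicate 2. Outside that stretch, chromosome 10 held 9 of 157 (5.73%) and 15 of 188 (7.98%), beside 6.15% and 6.44% of the peaks with lower pileups. Further groups, with neighbours within 100 kb, lay on chromosome 12 from 5619081 to 5652586 (16 peaks in replicate 1), on chromosome 1 from 33500730 to 33580646 (16 peaks), on chromosome 6 from 23563418 to 23587252 (13 peaks) and on chromosome 4 from 9114001 to 9184681 (12 peaks). The group on chromosome 4 contains the site enriched 6.32-fold and 6.03-fold.

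Some lay at the very ends of chromosomes. The first 20 kb of the chromosomes held 4 of the 184 such peaks of replicate 1 against 7 of the other 15796 (odds ratio 50.1, two-sided Fisher's exact p = 5.27e-06), and 5 of 223 against 2 of 21224 in replicate 2 (odds ratio 243, Fisher's exact p = 2.4e-09). The positions prompted this test and the lists share a control, so the p-values describe these lists and are not independent evidence. Of the 10 highest pileups in each list, 7 lay in the first 20 kb of a chromosome or were its last peak. The highest were 498 fragments at 31247567 to 31247768 on chromosome 6 in replicate 1, at 3.04-fold enrichment, and 583 at 65 to 320 on chromosome 2 in replicate 2, at 3.30-fold.

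For the excess of shared peaks over shifted lists, the part played by the shared GFP-Halo control could not be decided. On the lowest background in both lists the background that enters the fold is a constant and cannot order the peaks. Fold enrichment still correlated there between replicates (rho 0.208, 95% interval 0.155 to 0.259, 1304 pairs), against -0.00824 for pairs formed by shifts on that background. Division by a shared background therefore does not account for this agreement in strength. GFP-Halo coverage below that lowest level is not seen in the deposited values, so whether it differs among these sites was not tested. The correlation ranks pairs already shared and counts no overlaps, so it cannot tell how many overlaps the control created. Regional density on scales above 5 kb is argued against, because after shifts of only 5 to 50 kb the observed overlaps were 12.3 times the mean and above the highest of 279. Shifts of that size cannot test a bias on the scale of single sites. Part of the excess may come from the control, and a difference in preparation between the OsWRKY11-Halo and GFP-Halo reactions was not tested. OsWRKY11 binding to its own sites is the hypothesis the design names, and it was not tested by motif here.

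For the peaks with a pileup of at least 40, a candidate explanation is sequence over-represented in the genomic DNA library, such as collapsed repeats or organelle DNA with nuclear copies; rice chromosome 10 is known to carry a long plastid insertion, whose place in these coordinates was not examined. It stays open: the background was at least 3 times the lowest under 100% of these peaks in both lists, but a lower one would need a fold of at least 4.22 and 4.02, reached by 2.15% and 1.68% of all peaks, so that selection by pileup nearly fixes this value, and no sequence was tested. Local OsWRKY11 binding on top of the raised background stays open too: the 137 shared peaks of this kind had a median lower fold of 2.36 (bootstrap 95% interval 2.28 to 2.43) against 2.81 for other shared peaks, which the test set in advance would have counted against it. That bound was judged wrong only once its result was seen, because the lists hold folds down to 2.00 on raised background but none under 2.30 and 2.21 on the lowest, so that calling thresholds can set the medians apart. Their folds correlated between replicates (rho 0.655, 0.547 to 0.741), which either explanation allows. Both folds of a pair rest on the same GFP-Halo background, so part of this rho may come from the control.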
